A study of Mus musculus with 28 samples.

How the data were processed

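The series measured polyadenylated RNA from mouse retina by bulk RNA sequencing, with both eyes of each of 14 mice, 28 labelled samples in all. Per the labels, the right optic nerve was crushed (ONC) and the left was left intact (CTRL). Each mouse of either sex received vehicle or 10 mg/kg RGFP966, an inhibitor of the histone deacetylase HDAC3, by daily intraperitoneal injection for 7 days. Retinas were collected 7 days after the crush. For RGFP966 CTRL female A the free-text description mentions crush, whereas its title and condition say uncrushed; the latter were used, and this library lay at -24.0 on principal component 2, with the uncrushed eyes. Crush was always on the right side, so side and crush were one and the same factor here. Per the submitters' processing notes, libraries were made with an NEBNext kit, reads were assigned to mm10 transcripts with kallisto 0.46.1, and counts were normalized with DESeq2. The DESeq2 version, the trimming of reads and the sequencing batches are not given in the sources used here.

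The deposited file is a table of signal, which the authors describe as DESeq2-normalized counts, with 35999 genes in 28 columns. The values were checked against that description. They are not negative, they sum to 17700000 to 21900000 per library used (median 18700000), and within a library the low values fall on a common step, the value of about 1 read. Within 0.05 of a whole multiple of that step lay 44.6 to 64.1% of the values up to 20 reads (median 55.7%), so whole reads could not be recovered and tests on read counts were not run. Dividing the totals by the step gave an estimated depth of 16100000 to 24700000 reads per library (median 19500000). Between 19135 and 20170 genes per library had a value above 0 (median 19783).

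One column name occurred 2 times in the table and the name of its partner eye did not occur. Neither the order nor the values of columns may settle such a name, so these 2 columns were not used here, and the 13 mice and 26 libraries that remained were analysed: 7 RGFP966 mice (3 females, 4 males) and 6 vehicle mice (2 females, 4 males). The table also held 26 entries whose gene symbols had been turned into calendar dates; they carried 0.115% of the total and were left out. The X-inactivation transcripts are not analysed here.

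Values were transformed as log2(value + 1). Fold changes on this scale understate the change of genes with low values. Genes with a mean normalized count of at least 10 over the 26 libraries were tested, 15773 in all, of which 15742 were located in the GENCODE vM21 annotation of GRCm38 (mm10). Linear models were fitted with limma 3.58.1 (R 4.3.3) with empirical Bayes moderation and a trended prior. All tests were two-sided. A model of the 4 treatment-by-crush groups plus sex gave the effect of crush in vehicle mice, the effect of crush in RGFP966 mice, the effect of RGFP966 in crushed and in uncrushed eyes, and the drug by crush interaction. A model of the 8 treatment-by-crush-by-sex groups gave the sex by crush interaction, the sex by drug interaction in crushed eyes, and male against female. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with an adjusted p under 0.05 as the threshold. Errors of log2 fold changes are standard errors (SE) from limma. Errors of levels are standard deviations (SD).

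The comparisons, the gene lists, the rule for naming genes and all alternatives not marked as later additions were chosen before the data were examined. The naming rule took, for each comparison, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 50, the same sign in females and in males fitted separately (in the 5 comparisons with sex as a covariate), and a symbol neither of the form Gm plus digits nor ending in Rik. It added up to 4 members of each gene list with the smallest p, the members behind list counts of up to 5, and Hdac3, Gfap, Lcn2, Serpina3n, C3, Rbpms, Pou4f1, Nefl, Atf3, Sprr1a, Aif1 and Ddx3y. Some genes that the rule names are not reported here.

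Lists with tested members, 43 in number, covered glial states, retinal cell types, injury and stress responses, immune genes, other tissues of the eye, HDAC genes, metabolism, RNA quality and handling. Some genes belong to several lists. For example, C3 and Serping1 are in the neuroinflammatory astrocyte and complement lists, and Gfap is in the pan-reactive and gliosis lists. Cxcl10 is in the pan-reactive and cytokine lists, and Cdkn1a in the p53 and glucocorticoid lists. H2-D1, H2-T23 and Psmb8 are in the neuroinflammatory and MHC class I lists, Vcam1 in the neuroinflammatory and cytokine lists, and C4b in the gliosis and complement lists. Results of lists that share genes are not independent. Many members of the astrocyte, complement and interferon lists are expressed by more than one retinal cell type. For each list the members past the threshold were counted over all genes tested and with p-values adjusted over the list alone. Each list was compared with the other genes by limma's camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a comparison. Camera with an estimated correlation served as an alternative, as did fry, which tests another hypothesis: that the list itself did not change, without reference to the other genes. After the data were seen, the drug label was also permuted over mice on the mean log2 level of each list, with all 1716 assignments of 13 mice (an exact test). The permutation took no account of sex, unlike the limma models.

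The samples are paired by mouse, with the eyes of a mouse matched by the treatment, sex and replicate letter of their titles. All results given per mouse, and the swaps of eyes within mice, rest on this match, which the values do not settle. After the group means were removed, the correlation between the 2 eyes of a mouse had a median of 0.00156 (-0.345 to 0.230) over 13 mice, and it was above 0.1 in 2 of them; the consensus correlation from limma was -0.0286. The mouse was therefore used as a block in an alternative. The other alternatives were pseudocounts of 0.5 and 5, no filter on the mean or a mean of at least 50, rescaling to the same upper quartile or to the same total, quantile normalization, robust empirical Bayes, array weights, no sex term, only the groups compared, a fold change of at least 1.5, a block of sex and replicate letter for the drug comparisons, and leaving out each of the 26 libraries in turn. Leaving out RGFP966 CTRL male A and vehicle CTRL male D together, which stood apart in lens and in rod genes, was added after the data were seen, as were leaving out RGFP966 CTRL male B and vehicle CTRL male D for C3 in the sex by crush interaction and restricting the sex comparison to chromosomes other than X and Y.

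The pipeline was tested on simulated data with the observed spread of each gene, with 200 of 15773 genes changed in each of 5 simulations. The changes were 1.5-, 2- or 4-fold. The adjusted threshold is stricter where fewer genes change, so the shares below can be too high for a comparison with few changed genes. Genes were drawn independently. Variation shared by many genes within a library was not simulated, so the shares below need not hold where it is present. In the comparison of crushed and uncrushed vehicle eyes it recovered 52.8% of 1.5-fold and 76.4% of 2-fold changes with 5.09% false calls. For RGFP966 against vehicle in crushed eyes the shares were 60.9%, 78.5% and 6.23%. For the drug by crush interaction they were 40.0%, 63.9% and 3.68%, and for male against female 72.2%, 88.7% and 4.92%. Summaries and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.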

Results

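Polyadenylated RNA of mouse retina was profiled 7 days after crush of the right optic nerve, an injury that damages the axons of retinal ganglion cells and leaves the left eye as an uninjured control within the animal. Mice received daily injections of vehicle or of 10 mg/kg RGFP966, an inhibitor of the histone deacetylase HDAC3, in a series on chemical modulators of astrocyte reactivity. The 26 libraries analysed came from both eyes of 13 mice. They comprised 7 crushed (ONC) and 7 uncrushed (CTRL) retinas from RGFP966 mice, each with 3 females and 4 males, and 6 of each from vehicle mice, with 2 females and 4 males. The normalized counts per library summed to 17700000 to 21900000 (median 18700000), from an estimated 16100000 to 24700000 reads. The 10 most abundant genes took 11.2 to 17.7% of the total (median 13.7%). Crush separated the samples along the component with the next largest variance after the leading one: all 13 crushed retinas lay on its positive side and all 13 uncrushed retinas on its negative side.

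**Figure D1:**
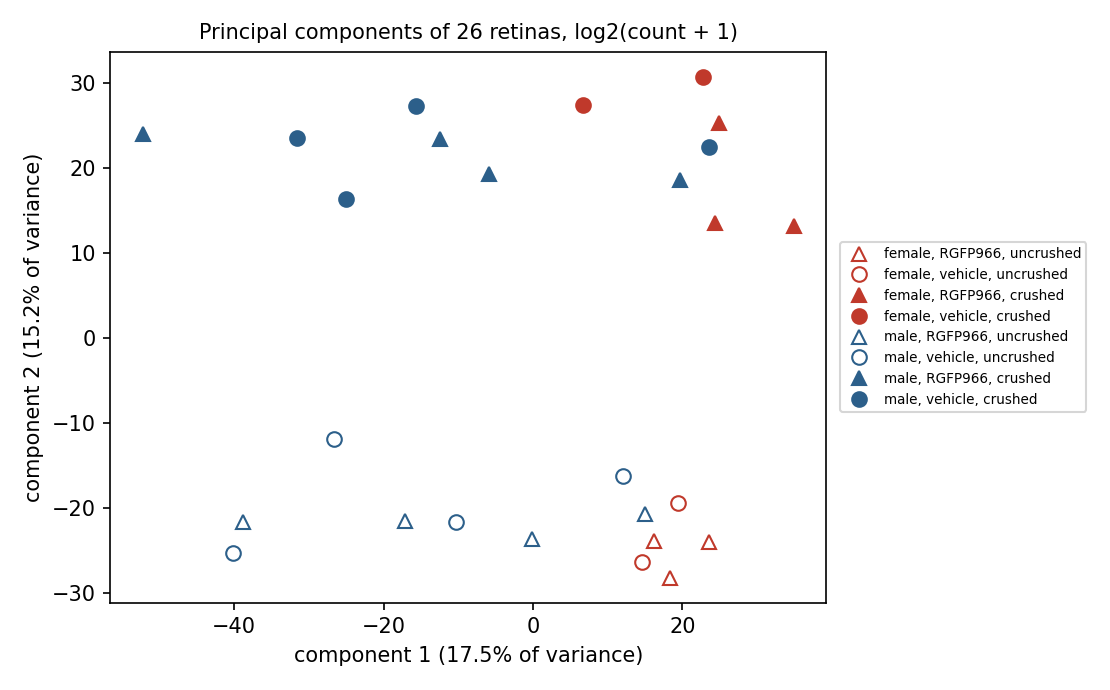
Principal components 1 (17.5% of variance, x axis) and 2 (15.2%, y axis) of log2(normalized count + 1), in arbitrary units, with each point 1 retina marked by treatment, crush and sex. The 13 crushed and 13 uncrushed retinas lie on opposite sides of 0 on component 2, whereas on component 1 the females lie between 6.63 and 34.9 and the males between -52.2 and 23.5.

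The comparison of crushed with uncrushed eyes in vehicle mice asks what the injury does to the retina without the drug. Retinal ganglion cell transcripts fell. Nefl encodes the light neurofilament of long axons (chromosome 14, 68083863 to 68089095 in mm10). It went from 6417 ± 1373 (SD, n = 6) to 1735 ± 504 normalized counts (n = 6), a log2 change of -1.91 ± 0.14 (SE; adjusted p = 5.6e-10). Glial and injury transcripts rose. Gfap, the intermediate filament of astrocytes and stressed Müller glia (chromosome 11, 102887336 to 102900912), went from 239 ± 79.1 to 1500.4 ± 383 (log2 change 2.68 ± 0.20, adjusted p = 5.6e-10). Ecel1, an endopeptidase induced in injured neurons (chromosome 1, 87147655 to 87156521), went from 7.03 ± 9.65 to 869.9 ± 247.5 (7.33 ± 0.41, adjusted p = 2.6e-12). The immune response included B2m, the light chain of MHC class I, which went from 423 ± 79.7 to 1622 ± 315 (1.94 ± 0.12, adjusted p = 3.1e-11).

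Of 24 measured retinal ganglion cell markers, 14 fell and none rose (17 fell when adjusted over the list alone), with a median of -0.88. Among them were the transcription factors Pou4f2 (-3.18 ± 0.32) and Pou4f1 (-2.38 ± 0.35, adjusted p = 3.5e-05; chromosome 14, 104461676 to 104467999), the RNA-binding protein Rbpms (-1.73 ± 0.18, adjusted p = 9.3e-08) and the calcium buffer Pvalb (-2.65 ± 0.25, adjusted p = 2.5e-08). Of 21 axon injury genes 11 rose and none fell (13 rose and 1 fell over the list alone), including Mmp12 (3.75 ± 0.34), Sox11 (2.27 ± 0.23) and Atf3 (1.15 ± 0.19, adjusted p = 1.4e-04), a transcription factor of the injury response. Sprr1a, a gene of regenerating neurons, was listed at 0 in 5 of 6 uncrushed vehicle retinas and at 8.66 in the other, and reached 103 ± 30.2 (n = 6) after crush. Of 20 genes of the integrated stress response 4 rose and none fell (7 rose over the list alone): Chac1 (adjusted p = 0.0046), Nupr1, Cebpb (0.66 ± 0.15) and Atf5 (0.40 ± 0.08). Of 17 p53 and apoptosis genes Cdkn1a (1.21 ± 0.28) and Phlda3 (0.79 ± 0.20) rose (3 over the list alone).

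Of 12 pan-reactive astrocyte genes 8 rose and none fell (11 over the list alone), with a median of 1.18. They included Cxcl10 (4.26 ± 0.56), Osmr (1.26 ± 0.18) and Vim (0.73 ± 0.10). Of 13 neuroinflammatory reactive astrocyte genes 8 rose (9 over the list alone), with a median of 0.81, among them Gbp2 (2.08 ± 0.18) and Serping1 (1.64 ± 0.21). Of 9 ischaemia-type reactive astrocyte genes S100a10 (0.67 ± 0.13) and Cd14 (1.68 ± 0.28) rose, also over the list alone. Of 7 retinal astrocyte markers Pdgfra (0.80 ± 0.22) and Aldh1l1 (0.60 ± 0.15) did, also over the list alone. Neither list passed as a whole (camera adjusted p = 0.068 and 0.091). The ischaemia-type list passed under 3 alternatives: no filter on the mean (0.0014), fry (0.0095), and without vehicle ONC male A (just under 0.05). The retinal astrocyte list passed with fry (0.039) and without vehicle CTRL male A (0.021) or vehicle ONC male D (0.039). Among 19 Müller gliosis genes 13 rose and 1 fell (16 and 1 over the list alone), with a median of 1.09. The rises included Fgf2, a survival factor for photoreceptors (2.16 ± 0.12, adjusted p = 2.6e-12), Edn2 (3.71 ± 0.29, adjusted p = 6.5e-10) and Stat3 (1.09 ± 0.08), and the fall was Mt3 (-0.43 ± 0.12). Of 13 Müller glia markers 5 rose, among them Clu (1.15 ± 0.13) and Crym (0.81 ± 0.09), and the glutamine synthetase Glul fell (-0.44 ± 0.09), with 8 rises and 2 falls over the list alone.

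Microglia markers rose in 16 of 17 cases (17 over the list alone), with a median of 1.46, including Ctss (2.01 ± 0.17), Itgam (1.70 ± 0.19) and Aif1 (1.49 ± 0.34, adjusted p = 0.0067). Of 15 activated microglia genes 9 rose (11 over the list alone), led by Cst7 (3.79 ± 0.43) and the lectin receptor Clec7a (3.24 ± 0.41). Of 17 complement genes 9 rose (11 over the list alone): C4b (2.21 ± 0.19) and the C1q chains C1qb (2.13 ± 0.17) and C1qc (2.02 ± 0.16) were among them. The interferon response rose in 22 of 25 genes (25 over the list alone), with a median of 1.46 and examples in Bst2 (2.21 ± 0.23), Rtp4 (2.05 ± 0.22) and Oasl2 (2.03 ± 0.17). MHC class I presentation rose in 12 of 14 genes (13 over the list alone), including H2-D1 (1.31 ± 0.09) and its regulator Nlrc5 (3.07 ± 0.47). Of 16 cytokine and NF-kB genes 10 rose, such as Ccl5 (3.12 ± 0.47) and Csf1 (1.05 ± 0.16), and 1 fell, with 13 and 1 over the list alone. The fall was that of the NF-kB inhibitor Tnfaip3 (-0.40 ± 0.09), a gene named after its value was seen because it was the only one to fall. Of 7 markers of other leukocytes 1 rose, the pan-leukocyte antigen Ptprc (1.97 ± 0.31).

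Rod genes fell in 6 of 15 cases (11 over the list alone), with a median of -0.28, among them Pde6g (-0.36 ± 0.09), Pde6b (-0.30 ± 0.07) and the rod transcription factor Nrl (-0.35 ± 0.10). The rod list passed camera (adjusted p = 6.9e-09; adjusted p = 0.19 with an estimated correlation), and its median went to 0.00 under quantile normalization. Cholesterol biosynthesis fell in 8 of 21 genes (13 over the list alone), including Fdps (-0.54 ± 0.09), Fdft1 (-0.41 ± 0.09) and Dhcr7 (-0.39 ± 0.09). Of 9 mitochondrially encoded genes mt-Atp6 fell (-0.53 ± 0.15; 9 over the list alone), with a list median of -0.43 (camera adjusted p = 2.6e-06; adjusted p = 0.19 with an estimated correlation) that became -0.05, no longer past the test, under quantile normalization. No oxidative phosphorylation gene passed (7 of 16 at an unadjusted p under 0.05 by limma; 3 fell over the list alone), with a median of -0.17 (adjusted p = 3.5e-05; adjusted p = 0.22 with an estimated correlation). Of 10 cone genes Gnb3, which ON bipolar cells also express, rose (1.02 ± 0.09; 1 rise and 2 falls over the list alone), and the list median was 0.03 (adjusted p = 0.69). Of 14 amacrine markers the calcium buffer Calb2, which ganglion cells also express, fell (-0.99 ± 0.25), with 1 rise and 1 fall over the list alone. The list median was 0.38 (adjusted p = 0.0097; adjusted p = 0.51 with an estimated correlation). No bipolar marker passed (1 of 15 at an unadjusted p under 0.05 by limma), with a median of 0.15 (adjusted p = 0.037; adjusted p = 0.45 with an estimated correlation). The amacrine call ended without vehicle CTRL male C (adjusted p = 0.059) or D (0.27). The bipolar call ended without vehicle CTRL male C (0.11) or D (0.31) or vehicle ONC male C (0.089).

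Other tissues and handling gave few changes with crush. No member passed by limma in the lists for horizontal cells (0 of 5 at an unadjusted p under 0.05), endothelial cells (1 of 12), pericytes and smooth muscle (1 of 9), retinal pigment epithelium (0 of 9), lens (0 of 16), cornea and ciliary epithelium (0 of 3), skeletal muscle (0 of 4) or red blood cells (0 of 5). The same held for oligodendrocytes (1 of 5, Cnp, which rose over the list alone), the HDAC3 corepressor complex (0 of 6), other histone deacetylases (1 of 10), fatty acid oxidation (1 of 12), the circadian clock (1 of 15), the cell cycle (1 of 10) and Y-linked genes (0 of 4). None of these lists passed camera except red blood cells (median -1.45, adjusted p = 0.043; adjusted p = 0.45 with an estimated correlation), a list that differed widely between mice. The pericyte list passed without vehicle ONC male B (adjusted p = 0.048). The red blood cell call ended without any 1 of 7 libraries: vehicle ONC female A, vehicle CTRL female C, vehicle ONC male A, vehicle ONC male B, vehicle CTRL male B, vehicle CTRL male C or vehicle CTRL male D (adjusted p = 0.079 to 0.16). Among immediate early genes Fosb (1.16 ± 0.24) and Junb rose and Dusp5 fell (-0.39 ± 0.10). Bag3 rose among 10 heat shock genes (0.90 ± 0.12) and Cdkn1a among 10 glucocorticoid genes. Sparc (0.89 ± 0.08) and Mmp14 (0.67 ± 0.20) rose among 19 matrix genes (3 over the list alone). The immediate early, heat shock and glucocorticoid lists did not pass camera (adjusted p = 0.067, 0.46 and 0.73). The immediate early list passed under 7 of 37 alternatives, among them leaving out any 1 of 4 libraries: vehicle ONC female A, vehicle CTRL female C, vehicle ONC male A or vehicle CTRL male D (adjusted p = 0.027 to 0.041). The matrix list did (adjusted p = 0.038; adjusted p = 0.40 with an estimated correlation), but not without vehicle ONC female A, vehicle CTRL male B, vehicle ONC male C, vehicle CTRL male D or vehicle ONC male D (adjusted p = 0.068 to 0.16). Hdac3 itself (chromosome 18, 37935844 to 37955016) was at 1429 ± 258 in uncrushed and 1313 ± 209 in crushed vehicle retinas (-0.12 ± 0.10, adjusted p = 0.65).

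By limma, 842 of 15773 genes passed in vehicle mice, 582 higher and 260 lower after crush, of which 433 and 80 changed at least 1.5-fold. Rescaling the libraries to the same total moved the median of all genes by 0.115, and 91.1% of 1073 called genes then rose, against 69.1% as deposited. With camera and an estimated correlation, the pan-reactive, neuroinflammatory, gliosis, ganglion cell, axon injury, integrated stress, microglia, activated microglia, complement, interferon, MHC class I, cytokine and cholesterol lists kept an adjusted p of at most 0.031. The Müller glia list (adjusted p = 1.3e-06) and the p53 list (0.037) did not (adjusted p = 0.051 and 0.052 with an estimated correlation), and the p53 call also ended without vehicle CTRL female A, vehicle ONC female C, vehicle CTRL male A, vehicle ONC male A or vehicle CTRL male B (adjusted p = 0.053 to 0.070). C3 rose by 1.70 ± 0.51 and Serpina3n by 1.49 ± 0.44 (adjusted p = 0.045 for each), close to the threshold, and C3 had an adjusted p of 0.078 with the mouse as a block. With no filter on the mean neither passed (C3 0.083, Serpina3n 0.078), nor under quantile normalization (0.077 and 0.062), and Serpina3n did not pass with robust empirical Bayes (0.056) or with only the groups compared (0.15). The C3 call ended without any 1 of 15 libraries (adjusted p = 0.051 to 0.11): vehicle CTRL female A or C, vehicle ONC female A or C, vehicle CTRL male A, B or C, vehicle ONC male B, C or D, RGFP966 CTRL female A, RGFP966 CTRL male A, C or D, or RGFP966 ONC male B. The Serpina3n call ended without any 1 of 14 (adjusted p = 0.050 to 0.13): vehicle CTRL female A or C, vehicle ONC female A or C, vehicle CTRL male B or D, vehicle ONC male A, B or C, RGFP966 CTRL female B, RGFP966 CTRL male D, or RGFP966 ONC male A, B or D. Over all 26 omissions its log2 change ran from 1.26 to 1.95 and its adjusted p by limma from 0.0010 to 0.13.

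**Figure D2:**
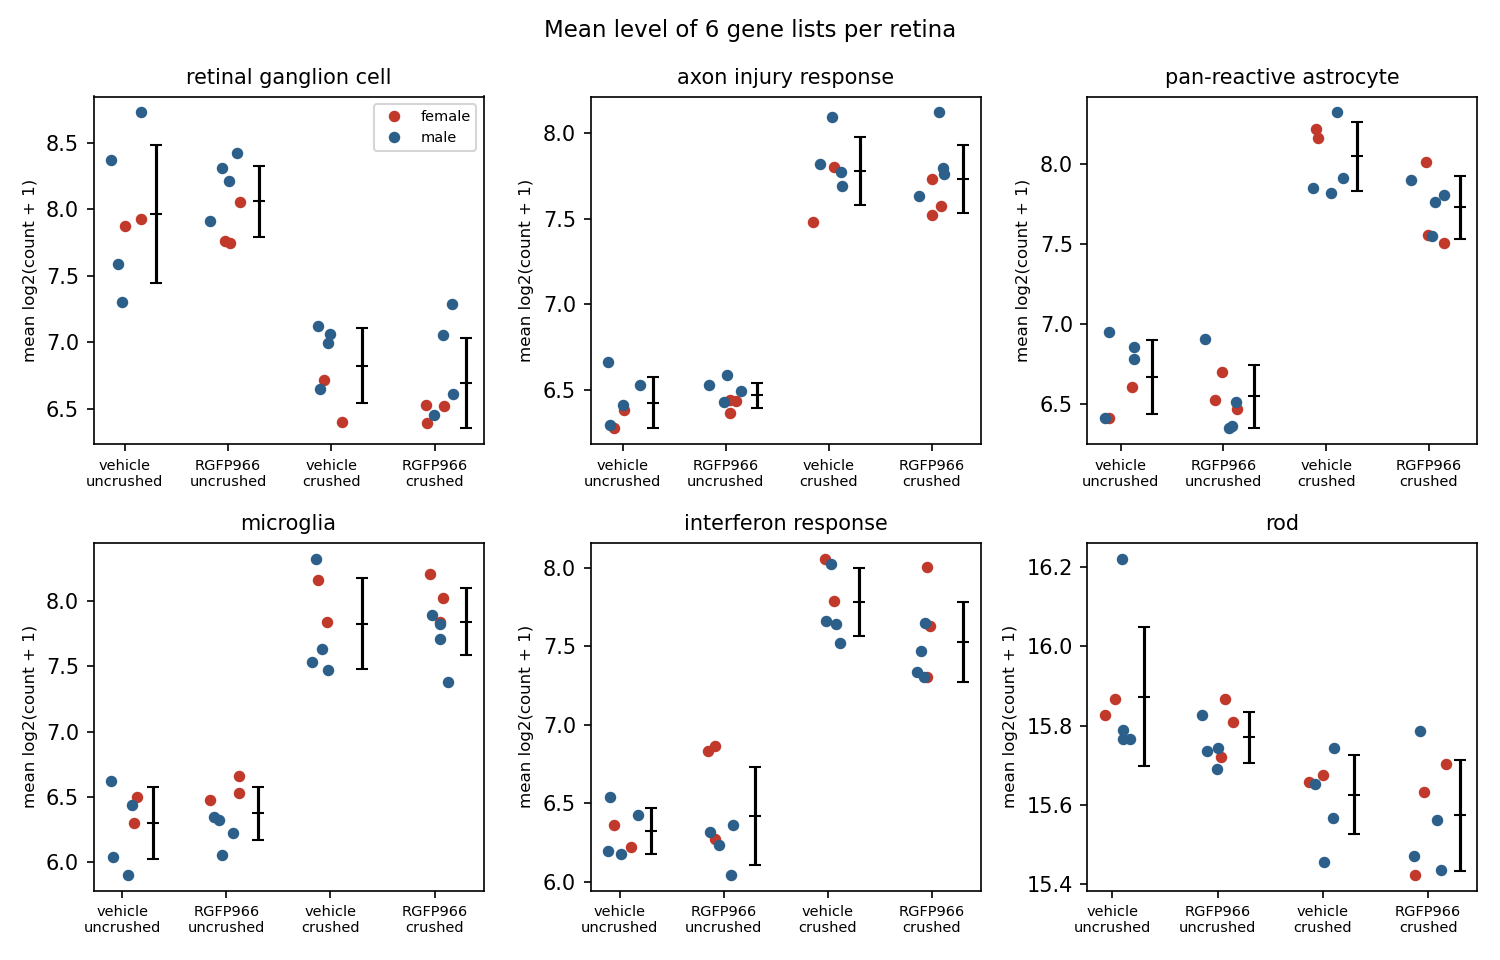
Mean log2(normalized count + 1) of the genes of 6 lists (y axis) in each retina (points, red for females and blue for males) of the 4 treatment and crush groups (x axis), with bars for the mean ± SD. Ganglion cell markers were lower and axon injury, pan-reactive, microglia and interferon genes higher in the crushed eye of 13 of 13 mice; rod genes were lower in 12 of 13, a fall whose median went to 0.00 in vehicle mice under quantile normalization.

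The comparison of crushed with uncrushed eyes in RGFP966 mice asks what the injury does under the drug. Ganglion cell transcripts fell here too. Nefl went from 6097 ± 1156 (SD, n = 7) to 1570.1 ± 473 (n = 7; -1.99 ± 0.13, SE, adjusted p = 4.5e-11) and Pou4f1 fell as well (-2.69 ± 0.33, adjusted p = 1.6e-06). The injury gene Ecel1 rose by 7.20 ± 0.38 (adjusted p = 6.5e-13). Gfap went from 266 ± 60.6 to 1089 ± 178, a rise of 2.04 ± 0.19 (adjusted p = 1.5e-08). Serpina3n, an acute-phase protease inhibitor of reactive astrocytes, rose from 62.8 ± 28.1 to 341 ± 124 (2.45 ± 0.41, adjusted p = 1.9e-04). C3 went from 26.2 ± 24.9 to 69.1 ± 49.4 (1.41 ± 0.47, adjusted p = 0.090) and passed with array weights (adjusted p = 0.021) and without RGFP966 CTRL male B (adjusted p = 0.013) or RGFP966 ONC male A (0.036). Hdac3 was at 1467 ± 238 and 1347 ± 252 (-0.13 ± 0.10, adjusted p = 0.61).

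Of 24 ganglion cell markers 16 fell (20 over the list alone), with a median of -1.18, including Pvalb (-3.01 ± 0.23) and Rbpms (-1.69 ± 0.16). Of 21 axon injury genes 10 rose (11 rose and 1 fell over the list alone), Atf3 among them (1.29 ± 0.18), and of 20 integrated stress genes 4 did (6 over the list alone), including Nupr1 (1.13 ± 0.15). In the glial lists 8 of 12 pan-reactive genes rose (10 over the list alone; median 0.79), 6 of 13 neuroinflammatory genes (9; median 0.69), and 14 of 19 gliosis genes (16, with 1 fall; median 1.19), such as Fgf2 (1.85 ± 0.11) and Edn2 (3.28 ± 0.27). Microglia markers rose in 15 of 17 cases (17 over the list alone). Activated microglia genes rose in 12 of 15 (13, with 1 fall), led by Itgax (4.46 ± 0.51) and Clec7a (3.89 ± 0.38), and complement genes in 8 of 17 (10). Interferon genes rose in 20 of 25 cases (22 over the list alone; median 1.23), MHC class I genes in 11 of 14 (11; median 0.96) and cytokine genes in 8 of 16, with 1 fall (10 and 1). Cholesterol biosynthesis fell in 4 of 21 genes (10 over the list alone), among them Fdps (-0.41 ± 0.09) and Fdft1 (-0.36 ± 0.08). Rod genes Pde6g (-0.34) and Nrl (-0.32) fell (10 of 15 over the list alone; median -0.23, or -0.02 under quantile normalization), with a camera adjusted p of 3.7e-07 (adjusted p = 0.26 with an estimated correlation). Gnb3 was again the cone gene that rose (0.74 ± 0.08), and Calb2 the amacrine marker that fell (-1.22 ± 0.23). Among the smaller lists, S100a10 (0.59 ± 0.12) and Cd14 of the ischaemia type, Aldh1l1 (0.56 ± 0.14) of retinal astrocytes, Cdkn1a (1.04 ± 0.26) of p53 and apoptosis, Ptprc (1.94 ± 0.28) and the uncoupling protein Ucp2 (0.72 ± 0.21) rose. Of these and other small lists, several did not pass camera as reported but did under alternatives. They were other leukocytes (median 0.52, adjusted p = 0.054; passed under 10 of 36 alternatives), matrix (0.28, 0.080; 6 of 37) and ischaemia-type genes (0.30, 0.084; 4 of 37). They were also pigment epithelium (0.61, 0.25; 3 of 37) and lens genes (0.45, 0.60; 2 of 37), the lens list with a median of 1.66 without RGFP966 CTRL male A (adjusted p = 5.9e-05). Oligodendrocyte genes passed with fry (0.015), and endothelial (0.042) and pericyte genes (0.043) without RGFP966 ONC female B.

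By limma, 737 genes passed in RGFP966 mice, 527 higher and 210 lower, of which 482 changed at least 1.5-fold. The vehicle and RGFP966 log2 changes were taken between different libraries. In both, 409 genes rose (19.4 would by independent draws) and 131 fell (3.46), with 0 called in opposite directions. The calls are not independent, since both used 1 estimate of each gene's spread from all 26 libraries. Genes with a small spread pass more readily in both, so independent draws are too low a baseline. Of the 842 genes called in vehicle mice 837 had the same sign in RGFP966 mice, and the log2 changes correlated at r = 0.955 across these genes, which were picked by their vehicle call, and at r = 0.712 across all 15773 genes tested; genes are not independent replicates. With an estimated correlation the lists that held in vehicle mice held here as well, with the p53 list added (largest adjusted p = 0.041, for cholesterol). The Müller glia (adjusted p = 3.4e-04), oxidative phosphorylation (1.2e-04) and mitochondrially encoded lists (0.0077) did not (adjusted p = 0.17, 0.26 and 0.50 with an estimated correlation). The mitochondrially encoded call also ended with fry (adjusted p = 0.22), without RGFP966 ONC male C (0.064) and under quantile normalization (0.51), where its median went from -0.23 to -0.04. With the same total per library, 85.4% of 884 called genes rose, against 71.5% as deposited. Serpine3 rose by 3.24 ± 0.88 (adjusted p = 0.028). Its log2 change stayed between 2.92 and 3.55 without any 1 of the 26 libraries, but it no longer passed with no filter on the mean or without any 1 of 7: RGFP966 CTRL female A or B, RGFP966 ONC female B or C, RGFP966 CTRL male B or D, or RGFP966 ONC male D (adjusted p = 0.056 to 0.077).

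**Figure D3:**
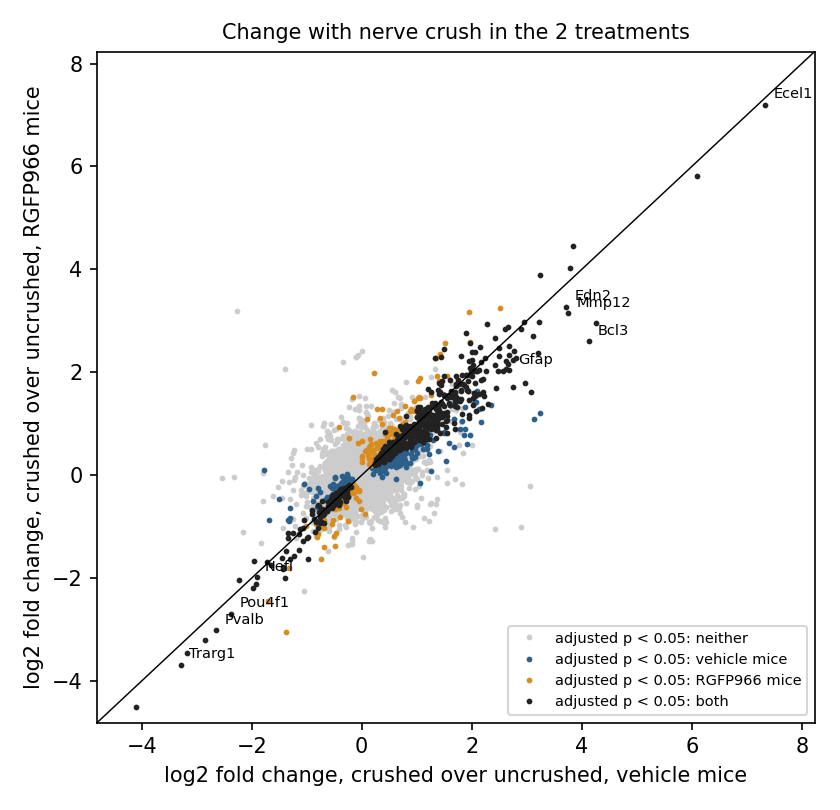
Log2 fold change of crushed against uncrushed eyes for each tested gene in vehicle mice (x axis) and in RGFP966 mice (y axis), with points coloured by an adjusted p under 0.05 in neither, in vehicle, in RGFP966 or in both, and a line of equality. Of the 842 genes called in vehicle mice 837 have the same sign in RGFP966 mice.

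The effect of RGFP966 in crushed eyes is the comparison in which a drug that alters astrocyte reactivity would show after injury. No gene passed the test in crushed eyes. Gfap was at 1089 ± 178 (SD, n = 7) in RGFP966 and 1500.4 ± 383 (n = 6) in vehicle crushed retinas (log2 difference -0.44 ± 0.20, SE). Lcn2, an iron-binding acute-phase protein, was at 100.4 ± 12.7 and 152 ± 69.4 (-0.48 ± 0.24), and Serpina3n at 341 ± 124 and 555 ± 209 (-0.68 ± 0.43). Lcn2 had not passed with crush in vehicle (log2 change 0.49) or RGFP966 mice (0.02), as reported or under any of 40 alternatives. Hdac3 stood at 1347 ± 252 and 1313 ± 209. Ganglion cell transcripts did not differ by more than their errors (Nefl -0.10 ± 0.14, Rbpms 0.06 ± 0.17, Pou4f1 0.01 ± 0.34), nor did Atf3 (0.10 ± 0.18), and Aif1 (0.37 ± 0.33) did not pass.

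Interferon response genes were lower in 24 of 25 cases under RGFP966 in crushed eyes, with a median of -0.23, as in Ifi44 (-1.07 ± 0.37), Oasl2 (-0.46 ± 0.17) and Cmpk2 (-0.43 ± 0.16). The list passed camera with its preset correlation (adjusted p = 2.2e-08), but not with an estimated one (adjusted p = 0.20 with an estimated correlation), nor fry (adjusted p = 0.45), which tests the list against no change rather than against other genes. Pan-reactive astrocyte genes were lower in 11 of 12 cases, with a median of -0.33 (adjusted p = 4.8e-04; adjusted p = 0.13 with an estimated correlation), and neuroinflammatory genes in 11 of 13 (-0.12; 0.0060; adjusted p = 0.17 with an estimated correlation). MHC class I (-0.11, adjusted p = 0.011), Müller glia (-0.15, 0.018), gliosis (-0.15, 0.024) and rod genes (-0.06, 0.045) were lower, and cone (0.17, 0.0017), mitochondrially encoded (0.17, 0.0017) and lens genes (1.11, 0.0022) higher. None of these held with an estimated correlation (adjusted p = 0.48, 0.79, 0.48, 0.93, 0.48, 0.79 and 0.85 in that order). Lens levels varied between single libraries of every group, and the lens call ended without RGFP966 ONC male A (adjusted p = 0.10). Ganglion cell (-0.07, adjusted p = 0.29), microglia (-0.02, 0.94) and axon injury genes (adjusted p = 0.87) did not pass. The ganglion cell list passed without vehicle ONC female A (-0.11, adjusted p = 0.034) or RGFP966 ONC male C (-0.19, 0.024). Endothelial genes passed, higher under RGFP966, without RGFP966 ONC female B (0.24, 1.3e-04), vehicle ONC female A (0.16, 0.034), RGFP966 ONC male C (0.24, 0.024) or vehicle ONC male D (0.24, 0.020). Pericyte genes did so without RGFP966 ONC female B (0.23, 0.0022) or vehicle ONC male A (0.24, 0.015). Oxidative phosphorylation (-0.07, 0.023), amacrine (-0.18, 0.032) and bipolar genes (0.09, 0.048) passed without 1 library each: RGFP966 ONC female B, RGFP966 ONC male C and RGFP966 ONC male A in that order.

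In all 43 lists, no member passed over the list alone except the Y-linked Ddx3y (-0.60 ± 0.17). Ddx3y had only low counts in females, and over the alternatives its value ran from -1.21 to -0.46. In crushed males the Y-linked list means of both treatments overlapped (9.96 to 10.04 under RGFP966, 9.79 to 10.06 under vehicle). The Ddx3y value thus cannot be read apart from the low counts in females. Single libraries ended several of the preset camera calls. These were vehicle ONC female A for the neuroinflammatory list (adjusted p = 0.065) and vehicle ONC male D for the cone list (0.055). They were vehicle ONC female C (0.27) or RGFP966 ONC male A (0.23) for the mitochondrially encoded list. For MHC class I they were vehicle ONC female A (0.27), RGFP966 ONC male A (0.065), RGFP966 ONC male C (0.13) and vehicle ONC male D (0.083). For gliosis they were vehicle ONC female C (0.30), RGFP966 ONC male C (0.15), RGFP966 ONC male D (0.070) and vehicle ONC male B (0.18). The Müller glia call ended without any 1 of 7 libraries (adjusted p = 0.069 to 0.23) and the rod call without any 1 of 17 (0.051 to 0.49). List means were also compared over mice by an exact permutation test, two-sided and added after the data were seen. Pan-reactive genes were at 7.73 ± 0.195 (SD, n = 7) against 8.05 ± 0.214 (n = 6; exact p = 0.0221, adjusted over 43 lists 0.952), and interferon genes at 7.53 ± 0.256 against 7.78 ± 0.218 (exact p = 0.0862, adjusted 0.997).

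By limma, 0 of 15773 genes passed for RGFP966 in crushed eyes, with 403 at an unadjusted p under 0.05, where chance gives 788.65 on average. The median half-width over genes of the 95% confidence interval, not adjusted for the number of genes, was 0.27 on the log2 scale, a 1.21-fold change.

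**Figure D4:**
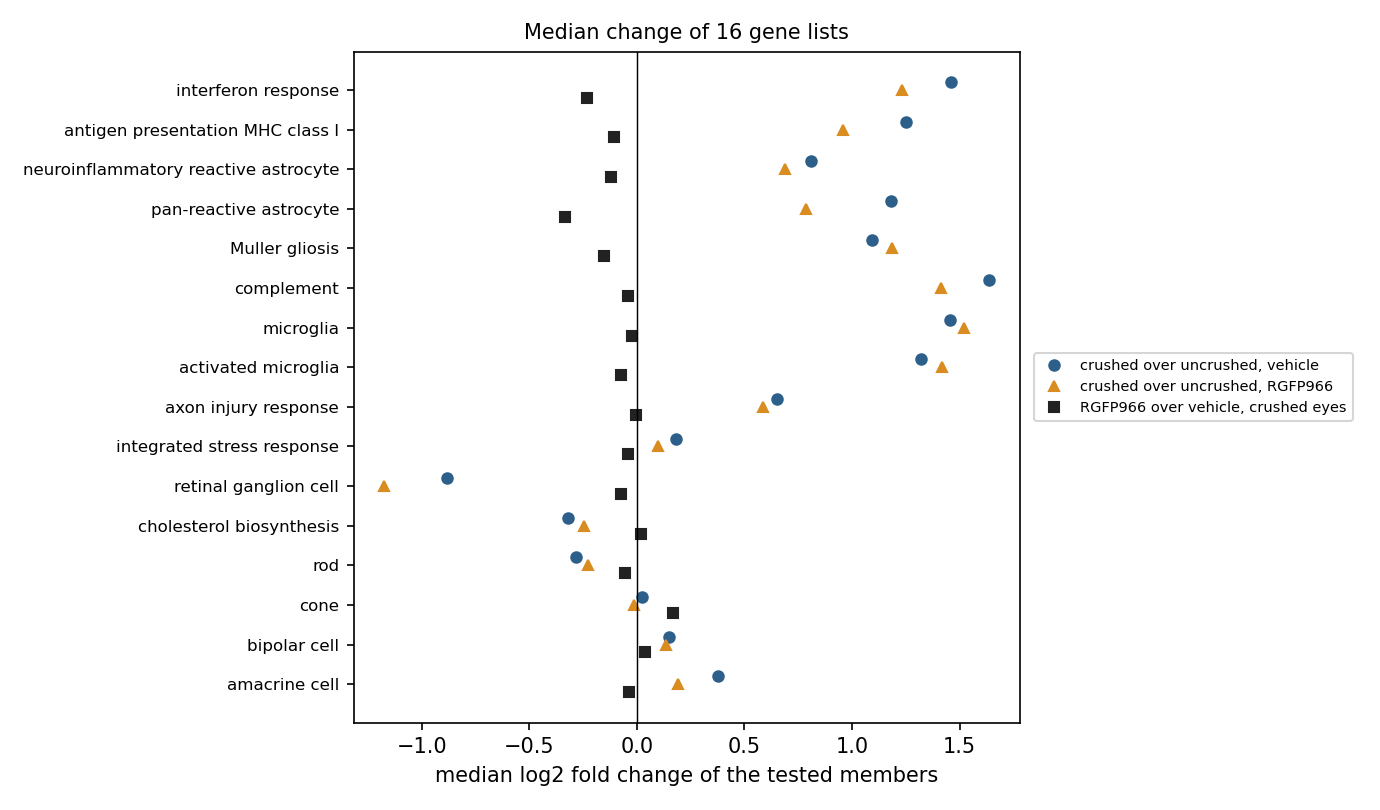
Median log2 fold change (x axis) of 16 gene lists (y axis) for crush in vehicle mice, crush in RGFP966 mice and RGFP966 against vehicle in crushed eyes. The crush medians of the interferon list are 1.46 and 1.23 and its drug median is -0.23; the rod medians with crush, -0.28 and -0.23, go to 0.00 and -0.02 under quantile normalization.

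In uncrushed eyes the comparison of RGFP966 with vehicle gives the effect of the drug on the uninjured retina, and no gene passed. Serpina3n was at 62.8 ± 28.1 (SD, n = 7) under RGFP966 and 289 ± 334 (n = 6) under vehicle, a log2 difference of -1.63 ± 0.43 (SE; adjusted p = 0.91), and it fell when adjusted over the pan-reactive list alone. The SD of the vehicle values exceeded their mean, and the same vehicle retinas enter the vehicle crush comparison of this gene. Over their lists alone Tgm1 (-1.91 ± 0.62), an ischaemia-type gene, also fell and Gbp2 (0.60 ± 0.18), a neuroinflammatory gene, rose. Hdac3 (0.01 ± 0.10) and Gfap (0.20 ± 0.20) did not pass.

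Rod genes were lower in 15 of 15 cases under RGFP966 in uncrushed eyes (median -0.12, camera adjusted p = 8.9e-04; adjusted p = 0.99 with an estimated correlation). Without vehicle CTRL male D, the library with the highest rod list mean (16.22 on the log2 scale), the rod median was -0.04 (adjusted p = 0.23), and under quantile normalization it was 0.01. Cone genes were higher in 10 of 10 cases (0.20, adjusted p = 8.9e-04; adjusted p = 0.66 with an estimated correlation), a call that also ended without that library (adjusted p = 0.051). Lens genes were higher (1.05, 0.033; adjusted p = 0.99 with an estimated correlation), but the call ended without any 1 of 7 libraries (adjusted p = 0.072 to 0.37), and their median was -0.33 without RGFP966 CTRL male A. MHC class I (0.18, 0.023), bipolar (0.09, 0.023), amacrine (0.14, 0.030) and pericyte genes (0.20, 0.030) were higher. Activated microglia (-0.24, 0.037), red blood cell (-1.24, 0.016) and glucocorticoid genes (-0.09, 0.023) were lower. None of these 7 lists held with an estimated correlation (adjusted p = 0.85, 0.91, 0.99, 0.91, 0.85, 0.91 and 0.66 in that order), and each call ended without single libraries, of which there were 4, 3, 5, 6, 8, 3 and 6. Lists that did not pass as reported but passed without single libraries were ganglion cell (5 libraries, adjusted p down to 6.8e-05), interferon (3, to 0.025), pigment epithelium (3, to 0.0059), oxidative phosphorylation (2, to 0.043) and endothelial genes (1, 0.034). By exact permutation of list means, the activated microglia list had the smallest p of the 43 lists (exact p = 0.0128, adjusted 0.551). By limma, 0 genes passed, with 782 at an unadjusted p under 0.05.

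The drug by crush interaction tests whether the injury response itself differed between RGFP966 and vehicle mice. Interferon genes had a lower crush response under RGFP966 in 24 of 25 cases (median -0.34, camera adjusted p = 4.4e-09; adjusted p = 0.16 with an estimated correlation) and MHC class I genes in 14 of 14 (-0.29, 2.3e-05; adjusted p = 0.14 with an estimated correlation). Neuroinflammatory genes had a median of -0.24 (0.0058; adjusted p = 0.14 with an estimated correlation), and Gbp2 (-0.84 ± 0.25) passed over that list alone. Of single genes with large crush responses, interaction values were -0.64 ± 0.28 (SE) for Gfap, 0.95 ± 0.60 for Serpina3n, -0.29 ± 0.69 for C3, -1.53 ± 0.73 for Bcl3 and -1.47 ± 0.63 for Nlrc5, and none passed. Ganglion cell genes were lower in 21 of 24 cases (-0.22, adjusted p = 0.0083; adjusted p = 0.91 with an estimated correlation).

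The other lists past camera in the interaction were mitochondrially encoded (0.20, adjusted p = 0.0083), pan-reactive (-0.22, 0.043), Müller glia (-0.14, 0.036), amacrine (-0.17, 0.029) and red blood cell genes (1.29, 0.029), with adjusted p = 0.91, 0.54, 0.91, 0.91 and 0.91 with an estimated correlation. These calls and that of the ganglion cell list ended without single libraries, of which there were 7, 16, 13, 11, 13 and 7 for the lists in that order, the ganglion cell list last. The ganglion cell median was -0.10 (adjusted p = 0.75) without vehicle CTRL male D, and the mitochondrially encoded one 0.03 (0.37) under quantile normalization. Pigment epithelium (5 libraries, adjusted p down to 0.0041), rod (2, to 0.035), lens (1, 5.9e-05) and bipolar genes (1, 0.044) did not pass as reported but passed without single libraries. In the exact permutation of list means the smallest p was that of MHC class I (exact p = 0.0280, adjusted 0.916). By limma, 0 genes passed the interaction, with 327 at an unadjusted p under 0.05, and the median half-width of the 95% confidence interval was 0.38.

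The genes called after crush in vehicle mice were also asked whether RGFP966 moved them back in crushed eyes. With the vehicle crushed libraries split between both contrasts, so that these shared no library, a median of 68.1% of the crush genes had a drug difference opposite to their crush change (43.5 to 81.4% over 20 splits). With the drug labels permuted over mice the median was 48.5% (24.6 to 76.7%), and 4 of 50 permutations reached 68.1%. Each permutation used a single split drawn at random, whereas 68.1% is the median over 20 splits. Single splits of the real labels spread from 43.5 to 81.4%. The 4 of 50 thus cannot tell how often such a median arises without a drug effect. Without the split, 77.9% of 842 genes were opposite, against a median of 66.6% under permuted labels, of which 5 of 50 permutations reached the observed share, and 67.0% in simulations with no drug effect.

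Sex was recorded for every mouse, and the comparison of males with females also checks the labels. Y-linked genes were higher in males. Ddx3y, an RNA helicase (chromosome Y, 1260771 to 1286629), was at 957 ± 84.8 (SD, n = 16) in males and 10.9 ± 4.70 (n = 10) in females (6.34 ± 0.09, SE, adjusted p = 5.3e-25). Here n counts retinas, both eyes of 8 males and of 5 females, each taken as a sample of its own. Eif2s3y, Kdm5d and Uty were higher by 9.69 ± 0.16, 3.23 ± 0.11 and 2.40 ± 0.10. Hdac3 was lower in males (1262 ± 199) than in females (1595 ± 104; -0.35 ± 0.08, adjusted p = 0.017), and Nefl higher (4349 ± 2689 against 3299 ± 2178; 0.44 ± 0.11, adjusted p = 0.023). Of the other named genes, the phosphatase Dusp4 was higher in males (1.22 ± 0.25). The matrix protein Hspg2 (-1.02 ± 0.20), Insl5 (-0.93 ± 0.20) and the pseudogene Mid1-ps1 (-3.62 ± 0.54) were lower. Reads of a pseudogene can come from its parent gene. Leaving out vehicle ONC female A ended the calls of Hdac3 (adjusted p = 0.079), Nefl (0.083), Dusp4 (0.063), Hspg2 (0.052) and Insl5 (0.083). Leaving out vehicle CTRL female A ended that of Nefl (0.061). Hdac3 and Nefl changed by less than 1.5-fold, so that threshold ended both calls.

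Beyond the 4 of 4 Y-linked genes, 7 of 9 mitochondrially encoded genes were lower in males (9 over the list alone; median -0.42, camera adjusted p = 5.1e-07; adjusted p = 0.47 with an estimated correlation). Under quantile normalization that median was -0.16, still past camera (adjusted p = 4.1e-05). Cone genes were higher in 6 of 10 cases (7; 0.35, 1.6e-05; adjusted p = 0.36 with an estimated correlation). Ganglion cell genes were higher in 3 of 24 (7, with 1 fall; 0.38, 6.1e-04; adjusted p = 0.84) and cholesterol genes in 4 of 21 (11; 0.17, 6.1e-04; adjusted p = 0.52). Heat shock genes were higher in 3 of 10 (6; 0.19, 0.0018; adjusted p = 0.47 with an estimated correlation) and amacrine genes in 3 of 14 (8; 0.44, 0.0022; adjusted p = 0.84). Microglia genes were lower in 1 of 17 cases (2; -0.24, 0.0021; adjusted p = 0.84 with an estimated correlation) and interferon genes in 2 of 25 (4; -0.24, 0.0092; adjusted p = 0.84), the latter not without RGFP966 ONC female C (adjusted p = 0.065). Circadian genes (0.08, adjusted p = 0.053) did not pass but did under 15 of 36 alternatives, 11 of them without 1 library. Lens genes (-1.06, 0.10) did under 8 of 36, 5 of them without 1 library (down to 1.2e-04). Axon injury genes passed under 2 of 36, and complement and other histone deacetylase genes under 1 of 36 each. Members that passed included Chat (0.90 ± 0.27) and Gad2 (0.72 ± 0.22) among amacrine markers, Idi1 (0.35 ± 0.10) and Cyp51 (0.23 ± 0.07) among cholesterol genes, Hspa5 (0.18 ± 0.05) among heat shock genes and Olfml3 (-0.33 ± 0.10) among microglia markers. Of 10 other histone deacetylases 2 were lower in males (6 lower and 2 higher over the list alone): Hdac7 (-0.46 ± 0.12) and Hdac1 (-0.21 ± 0.06), which lie outside the naming rule and were named after their values were seen, as were the interferon genes Irf7 (-0.37 ± 0.09) and Stat2 (-0.30 ± 0.08).

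By limma, 1261 genes differed between the sexes, 655 higher and 606 lower in males, and only 109 and 118 of them at least 1.5-fold. With the mouse as a block 1722 passed. That fit used a consensus correlation between eyes, which was -0.0286 in the model with sex as a covariate. A correlation below 0 counts 2 eyes as more than 2 independent samples, so a higher count is not stronger evidence. The share higher in males was 51.9% as deposited, 34.3% of 1184 genes with the same upper quartile and 76.0% of 1623 with the same total. The count rested on single libraries. It was 45 without vehicle ONC female A, 140 without vehicle CTRL female A and 302 without vehicle CTRL female C. It rose to 2324 without vehicle CTRL male C, 2607 without RGFP966 ONC male B and 2637 without vehicle ONC male D. It was 446 without RGFP966 ONC female A, and 484 and 536 without RGFP966 CTRL female B and C. It was 779 without RGFP966 ONC female B, 801 without RGFP966 CTRL female A and 805 without vehicle ONC female C. Among the other males it was 389 and 530.0 without RGFP966 CTRL male B and D, and 572 and 711 without RGFP966 ONC male C and D. It was 677 and 579 without vehicle CTRL male A and B, and 607, 412 and 551 without vehicle ONC male A, B and C.

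Whether the injury or the drug acted differently by sex was tested by interactions. In the sex by crush interaction, C3 had a value of -2.11 ± 0.58 (SE) and did not pass over all genes (adjusted p = 0.99998 by limma). It passed over the complement list (adjusted p = 0.022) and the neuroinflammatory list alone (0.016), whereas Gfap was at 0.07 ± 0.29. Both values are the same unadjusted p (0.0013) adjusted over 17 and 13 genes. They take no account of the number of lists and comparisons. C3 stood apart in 2 uncrushed males, RGFP966 CTRL male B (80.1, others of its group 6.87 to 25.8) and vehicle CTRL male D (69.9, others 14.8 to 29.2). Without both, a test added after the data were seen, the value was -1.64 ± 0.46 (adjusted p = 0.022 and 0.023 over these lists alone). It did not pass over either list without vehicle CTRL female A (0.085 and 0.065) or vehicle ONC female A (0.11 and 0.086), nor over the complement list without RGFP966 ONC female C, where the adjusted p lay just above 0.05. Red blood cell (median -2.28, camera adjusted p = 2.7e-04), complement (-0.16, 0.0034), oxidative phosphorylation (-0.12, 0.0040), Müller glia (0.08, 0.020) and mitochondrially encoded genes (0.22, 0.030) passed camera, with adjusted p = 0.66, 0.66, 0.75, 0.68 and 0.79 with an estimated correlation. By limma 0 genes passed, with 382 at an unadjusted p under 0.05. In the sex by drug interaction in crushed eyes Ddx3y was at 1.24 ± 0.25 (adjusted p = 0.24) and passed over the Y-linked list alone, as did Dbp (-0.41 ± 0.12) of the circadian list, Hspa5 (0.43 ± 0.14) of the heat shock list and Ndufa1 (-1.08 ± 0.29), named after its value was seen, of the oxidative phosphorylation list. The Ddx3y value sets males against females with only low counts of this gene (2 vehicle and 3 RGFP966 crushed females). Serpina3n (0.76 ± 0.86) and Gfap (0.30 ± 0.42) did not pass. Oxidative phosphorylation passed camera (-0.19, 0.0034; adjusted p = 0.93 with an estimated correlation). By limma 0 genes passed, with 861 at an unadjusted p under 0.05; without RGFP966 ONC female C, 1 did. The median half-widths of the 95% confidence intervals were 0.40 and 0.56 on the log2 scale.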

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

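The tests of outlying libraries, of splits of the samples and of the explanations below were chosen after the results were seen, except that of a shared axis in the sex comparison, which was fixed beforehand. In 224 groups of values, 13 values of single libraries stood apart from the others of their group by the gap test of Dixon, where chance gives about 1 in 20 groups, or 11.2.

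Pattern 1 is the lower interferon response list under RGFP966 in crushed eyes (list mean -0.253 ± 0.131, SE, 7 against 6 mice). With mice reassigned to treatment without regard to sex, the exact permutation p of the list mean was 0.0862 (two-sided), so a chance assignment stays open. The tables exclude neither of the other explanations: the microglia list mean differed by 0.0128 ± 0.172, an interval that leaves room for fewer microglia, and the ganglion cell list mean by -0.133 ± 0.173, which leaves room for an injury of another severity. A drug effect on interferon genes stays open too, as a biological explanation that the design names and that this number of mice did not settle.

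Pattern 2 is the set of 1261 genes that differ between males and females. Of the called genes with a location 95.6% lay outside X and Y, so the set is not made up of X and Y genes alone. Where a gene lies does not tell whether X- or Y-linked genes caused its difference, so that source stays open. The leading axis of variation among male libraries (25.7% of their variance) correlated with the sex difference at 0.834 in size across the 1203 called autosomal genes, which are not independent replicates, and at 0.648 across all autosomal genes, so an axis that also separates libraries of one sex has the values it needs. The leading axes among males and among females correlated at only 0.103 in size. A biological sex difference outside the Y-linked genes, a technical difference between libraries, and their mixture stay open, and may not be separated by the 5 females and 8 males, given a count of 45 without vehicle ONC female A.

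Pattern 3 is the lower rod list in crushed eyes, lower in 12 of 13 mice (mean change -0.22 ± 0.198, SD). Dilution by RNA from cells that increased would lower rod and bipolar genes alike. The rod change minus the bipolar change had a mean of -0.365 (SE 0.0952, SD over mice 0.343) and was below 0 in 12 of 13 mice. On the scale as deposited this argues against dilution as the whole cause. The difference was not computed under quantile normalization. Vehicle CTRL male D, which has the highest rod list mean, is not the whole cause either, since the rod median in vehicle mice was -0.195 without it. Quantile normalization, which forces 1 distribution on all libraries, took the median to 0.00, and it stays open whether the scaling of very abundant genes or a loss of rod transcripts is a likely source.

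Other splits of the samples tested whether chance can give as many genes. For crush in vehicle mice 1 of 100 splits, the real one, gave as many (842 genes, highest other 202), and with eyes swapped within mice 1 of 32 (highest other 150). For crush in RGFP966 mice 1 of 100 splits did (737 genes, highest other 282), and 1 of 64 swaps (highest other 238). For male against female 1 of 100 splits did (1261, highest other 1010). For the crush comparisons no other split or swap came near the real count, which makes chance an unlikely source. The lowest share that could be reached was 1 of 100 splits and 1 of 32 or 64 swaps, so chance is not strictly excluded. For the sexes chance was less firmly set aside, since another split came near and the count was 45 without vehicle ONC female A. In the others the count was 0, which all 100 of 100 splits reach whatever the grouping, so the splits decided nothing: RGFP966 against vehicle in crushed eyes (highest other 33) and in uncrushed eyes (2), drug by crush (4), sex by crush (1), and sex by drug in crushed eyes (2058). The 2058 genes of that 1 split point to a structure of the samples that is not that of the groups, and what separates its samples was not tested.

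Libraries that stood apart were these, each with the range of the others of its treatment and crush group. C3 was at 80.1 normalized counts in RGFP966 CTRL male B (others 6.87 to 25.8). The lens list mean was 10.93 in RGFP966 CTRL male A (2.33 to 5.08) and 7.87 in vehicle CTRL female A (2.26 to 2.94). The heat shock list mean was 10.88 in RGFP966 CTRL male A (10.17 to 10.44). The cell cycle list mean was 6.56 in RGFP966 CTRL female C (6.71 to 6.81). The neuroinflammatory astrocyte list mean was 7.73 in RGFP966 ONC female C (7.24 to 7.44). In vehicle CTRL male D, Atf3 was at 207 (102 to 133), C3 at 69.9 (14.8 to 29.2), Sprr1a at 8.66 (all others at 0) and the rod list mean at 16.22 (15.77 to 15.87). Aif1 was at 91.8 in vehicle ONC male D (30.0 to 49.5). The oligodendrocyte list mean was 6.404 in vehicle ONC male B (6.72 to 6.85). The circadian list mean was 10.67 in vehicle ONC male C (10.53 to 10.56).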

How the results depend on the processing

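All settings were planned except leaving out RGFP966 CTRL male A and vehicle CTRL male D together, the exact permutation of list means, C3 in the sex by crush interaction without RGFP966 CTRL male B and vehicle CTRL male D, and the sex comparison on chromosomes other than X and Y, which were added after the data were seen. The tests on read counts with edgeR and DESeq2 were not run, since whole reads could not be recovered. Over 46 alternative settings, 26 of them leaving out 1 library, the counts stayed within 1.5 times of the reported one in 289 cases and moved further in 29. List results kept direction and side of the threshold in 9060 cases, fell short of it in 312, passed it anew in 110 and reversed in 3, by the direction of the test. Named genes did so in 5014 cases, fell short in 143 and passed anew in 5, and 20 of 131 named results lost the call somewhere. With the mouse as a block, 697 of the 842 vehicle crush genes and 634 of the 737 RGFP966 crush genes were called again. Gfap kept both crush calls under all 40 alternatives, with log2 changes of 2.52 to 2.80 in vehicle and 1.92 to 2.13 in RGFP966 mice.

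The crush counts ranged from 676 to 891 (vehicle) and from 630.0 to 838 (RGFP966) without 1 library. A fold change of at least 1.5 left 513 and 482 genes and 227 of the sex genes, fewer by construction. The count for RGFP966 in crushed eyes, in uncrushed eyes, for drug by crush and for sex by crush was 0 under every alternative run by limma. For sex by drug in crushed eyes it was 1 with no filter on the mean, 30 with array weights, and 0 to 1 without 1 library. For male against female it was 466 with no filter, 4244 with array weights, 1196 on chromosomes other than X and Y, and 45 to 2637 without 1 library. The cause was not tested, except that no filter means more genes tested. The rod list in vehicle crush lost its fall under quantile normalization, with a median of 0.00 (camera adjusted p = 0.82) and a test direction that had turned. The sign of the median turned in the lens list for RGFP966 in uncrushed eyes, -0.17 without RGFP966 CTRL male A and vehicle CTRL male D and -0.33 to 2.01 without 1 library, the low end without RGFP966 CTRL male A, the library with the highest lens level. For RGFP966 in crushed eyes the median half-width over genes of the unadjusted 95% confidence interval was 1.21-fold. In simulations with independent genes 60.9% of 1.5-fold changes passed the adjusted threshold. Variation shared across genes was not simulated, and what sets this limit was not tested. Each simulation changed 200 genes, some of them 4-fold. With fewer changed genes the adjusted threshold is stricter, so 60.9% can be too high for a drug effect on few genes.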

Other observations

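All tests in this part that are not in the report were chosen after the data were seen. Per mouse, the crushed eye differed from the other eye in the same direction in 13 of 13 mice for several list means. Axon injury genes were higher by 1.30 ± 0.172 (SD over mice, log2), microglia genes by 1.49 ± 0.274, activated microglia genes by 1.68 ± 0.418, Müller gliosis genes by 1.30 ± 0.261 and pan-reactive genes by 1.27 ± 0.388. Müller glia (0.31 ± 0.172), integrated stress (0.24 ± 0.094) and p53 genes (0.27 ± 0.141) moved less, also in all 13. Ganglion cell genes fell by 1.26 ± 0.357, and cholesterol biosynthesis genes fell by 0.27 ± 0.133, in all 13.

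Lists of tissues next to the retina varied widely from mouse to mouse, without a common direction over all 13 mice. Red blood cell genes were lower in the crushed eye of 9 mice, among them every male, and higher in 4, all females. The change of the lens list mean ran from -4.52 to 2.84 (SD 2.43) and that of red blood cell genes from -3.12 to 2.001 (SD 1.58), against an SD of 1.28 for pigment epithelium. The closest pair of libraries within a treatment, crush and sex group differed by a root mean square of 0.494 over genes on the log2 scale. The most distant pair of all libraries differed by 0.846. No library thus duplicated another of its own group, and pairs across groups were not checked for this.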
